A study of Arabidopsis thaliana with 12 samples.

How the data were processed

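RNA from whole Arabidopsis thaliana seedlings was measured on Affymetrix ATH1 arrays, a short-oligonucleotide design that reads each transcript with a group of probes called a probe set. The 12 arrays fell into 4 groups of 3 biological replicates: wild type and amiR-SNF4 seedlings, each grown in darkness or in light. Groups and replicate numbers were taken from the sample titles. Arrays of a group were called biological replicates in the titles, but the labels did not say whether they came from separate cultures, so p-values measure the spread between these samples.

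The deposited values were intensities on a linear scale, 1 per probe set and array, and the submitters' processing notes named GCOS, Affymetrix's array software, with no version. Whether the values had been scaled was not given in the sources used here. Array medians of the non-control probe sets ran from 39.4 to 99.5, a 2.52-fold range, and means trimmed by 2% at each end ran from 94.7 to 264, so the arrays were treated as not normalized. Detection calls were not used here, so signal over background was not known for single values. The stated precision rests on the number of arrays and the spread between them, and for dim genes also on the constant added before taking logs.

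Control probe sets (64 of 22810) were set aside. The remaining 22746 were quantile-normalized on the log2 scale, and log2(intensity + 16) was taken. Fold changes are therefore on the log2(intensity + 16) scale, which understates changes of dim genes. The design written before the data were examined had used the deposited intensities without normalization between arrays. Quantile normalization was chosen when the array medians were seen, before any test result, and the counts without it are given beside the main counts.

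Genes were named from the platform annotation given with the table, with symbols updated through the gene identifier against a gene table of the TAIR10.1 assembly, used for names only. Of the non-control probe sets, 13513 named 1 gene, 503 named several and were left out, and 8730 (38.4%) were unnamed here. For 146 genes with several probe sets the one with the highest mean over the 12 arrays was kept, which gave 13356 genes, 13286 of them matched to the gene table.

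All 12 arrays were fitted in 1 linear model with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and 5 contrasts were tested: amiR-SNF4 against wild type in darkness and in light, the difference between those effects, and light against darkness in each genotype. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Errors of fold changes are standard errors of this fit, with 1 spread per gene shared by all groups, so a gene has the same error in darkness and light. The median within-group SD was 0.261 in the dark and 0.173 in the light groups. Errors therefore tend to be understated in darkness and overstated in light. Gene lists with at least 3 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 31 lists of a contrast, with an estimated correlation and limma's fry test beside it. Camera compares a list with all other genes, whereas fry asks whether its members move, on balance, one way.

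The comparisons, tests, alternatives, 23 gene lists with 505 entries and the rule for naming genes were fixed before the data were examined. Of those entries, 87 were measured, so each list covers part of its pathway, and 17 lists had at least 3. Another 14 lists were drawn up after the annotation, but no fold change, had been seen. Those used in the Results are the pathogen and salicylate responsive loci, TIR-class receptors, ER translocation and beta-glucosidase lists. The others used there are the cytosolic and plastid ribosomal protein, photosystem and Calvin cycle, and mitochondrion-encoded lists. The naming rule took SNF4; the 5 largest rises and 5 largest falls of each genotype comparison among called genes whose 3 arrays did not overlap with the other 3; up to 2 called members of each list with the smallest adjusted p, or the member with the smallest p where none was called; the 5 smallest p-values of the difference; and the 3 largest rises and falls of each light comparison. CRT1b, BZIP17, BSMT1, WRKY22 and SBPASE fall outside the rule and were chosen after their values were seen; for other genes the value in a second comparison is given beside the one that named them.

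The fit was tested on simulated arrays with the observed means, spreads and array brightness, with 67, 67 and 66 of 13356 genes changed by 0.5, 1 and 2 on the log2 scale. In the simulated darkness comparison, 56.1% of genes changed by 2 on the log2 scale were recovered, 22.4% of those changed by 1 and 2.99% of those changed by 0.5, all in the right direction, with 4 unchanged genes called. In the simulated light comparison these shares were 48.5%, 23.9% and 5.97%. For the difference between effects, 19.7% of genes changed by 2 were recovered. Unchanged genes made up 6.25% of the genes called in the simulated darkness comparison, 3.39% in light and 0% for the difference. Between simulated light and darkness they made up 11.5% in wild type and 7.02% in amiR-SNF4. Simulated dark and light arrays had the same spread, and far fewer genes were changed than were called in the real data. The recovered shares therefore do not give the power of the real comparisons. A list shifted by 1 was called in each of the 5 simulated comparisons, and of 30 lists left unshifted 2 were called in the simulated darkness comparison and 0 in each of the others. Simulated genes varied independently of each other. In the real data the estimated correlation was 0.862 for plastid and 0.592 for cytosolic ribosomal protein genes. The simulated list counts therefore do not vouch for list calls at the preset correlation in the real data.

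Alternatives covered the normalization, the pseudocount (1 and 64), removal of the dimmest genes (33.3% of them), fits with only the groups compared, a replicate block, the variance prior, array weights, the probe sets tested, the threshold, and leaving out each array. Scaling to the bioC, bioD and cre hybridization controls was added after seeing the data, as were fits of only the 2 groups compared that kept the normalization over all 12 arrays. No pair of arrays held identical values, and the correlation of normalized signals between arrays of a group ran from 0.965 to 0.988.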

Results

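The study examined seedlings in which an inducible artificial microRNA, amiR-SNF4, silences SNF4, the activating subunit of the energy-sensing kinase SnRK1. Per the labels, seedlings of wild type and of the silenced line were raised at 22 °C on medium with 0.5% sucrose and 5 µM of the inducer β-estradiol, in darkness or under 8 h of light and 16 h of dark, and were collected 5 days after germination, 4 h into the light period. The labels of the light-grown samples alone also gave 7 days after sowing. The light intensity was given as 120 in the sample labels and as 400 in the series text. Each of the 4 groups had 3 arrays. Mean array medians of the deposited intensities were 54.2 ± 12.8 (SD, n = 3) in dark-grown wild type, 56.0 ± 5.71 in dark-grown amiR-SNF4, 81.1 ± 19.2 in light-grown wild type and 75.1 ± 9.53 in light-grown amiR-SNF4. The first 2 principal components held 44.6% and 34.0% of the variance after normalization. No probe set named SNF4 was among those analysed here, so the level of the silenced gene was not analysed here and the labels could not be checked against it. The samples held no amiR-SNF4 seedlings without the inducer and no other transgenic line. Effects of SNF4 loss therefore cannot be told apart from other effects of the line. Silencing, as used below, stands for the comparison of amiR-SNF4 with wild type.

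In dark-grown seedlings, silencing went with large rises of defence genes and falls of photosynthesis genes. The lipase-like gene SAG101, a partner of the immune regulator EDS1, rose 13.0-fold (log2 fold change 3.70 ± 0.15, SE, n = 3 arrays per group), the mitochondrial stress gene AT2G21640 (UPOX) rose 30.1-fold (4.91 ± 0.26), and ATERDJ3B, a chaperone of the endoplasmic reticulum (ER), rose 6.77-fold (2.76 ± 0.14). The light-harvesting gene LHCB4.2 fell by 2.15 ± 0.23 on the log2 scale. In all, 4113 of 13356 genes differed between amiR-SNF4 and wild type in darkness, 1911 higher and 2202 lower, and 1771 of them by at least 2-fold (920 higher, 851 lower). Of all 13356 genes, 4947 (37.0%) had no overlap between the 3 arrays of one genotype and those of the other, where chance gives 10%. Without normalization between arrays the count was 2282 (1321 higher, 961 lower), of which 2278 were called in the same direction with normalization. Scaling to the hybridization controls gave 2410 (1377 higher, 1033 lower).

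Among the named genes, the 5 largest rises in darkness were those of AT5G38910, a germin-like gene (192-fold), AT3G60420 (187-fold), AT1G21520 (159-fold), AT2G30670 (119-fold) and AT5G24210 (117-fold). Their wild-type signals lay between 4.14 and 5.73 on the log2 scale, close to the floor set by the added 16. Folds there are understated by unequal amounts, so the order of these rises is uncertain. The largest falls of named genes were those of the pectin methylesterase gene ATPMEPCRD (28.1-fold), the organic cation transporter gene OCT1 (22.9-fold), AT2G28780 (20.0-fold) and AT4G39675 (19.4-fold), and AT1G64370 fell by 4.12 on the log2 scale. In amiR-SNF4 OCT1 (4.35), AT2G28780 (4.78) and AT1G64370 (4.80) lay near the same floor. Their falls are therefore understated, and the order of the falls is uncertain. Adjusted p-values of these 10 genes ran from 7.48e-13 for AT3G60420 to 6.52e-08 for AT4G39675.

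Genes tied to salicylic acid and immunity rose in darkness. All 4 measured members of the salicylic acid response list were higher, 4 also when adjusted over the list alone, with a median log2 fold change of 2.27 (camera adjusted p = 7.40e-05, and 0.0219 with an estimated correlation). Among them GRX480, a glutaredoxin of salicylate signalling, rose by 2.68 ± 0.16 and AT5G52810 (SARD4, an enzyme of pipecolate synthesis) by 2.23 ± 0.18 on the log2 scale. Of 8 members of the innate immunity list, 5 rose (6 adjusted over the list alone) and none fell (camera adjusted p = 0.000122, and 0.0219 with an estimated correlation), with the smallest p-values for the transcription factor WRKY6 (2.87 ± 0.19) and the ubiquitin ligase PUB24 (1.19 ± 0.14). WRKY53 was at 0.21 ± 0.16 (adjusted p = 0.378). Of 30 measured pathogen and salicylate responsive loci, a list not among those planned, 24 rose and none fell (median 2.05, camera adjusted p = 1.26e-20, and 0.0138 with an estimated correlation). Among 55 receptors of the TIR class, a family of intracellular immune receptors, 23 rose and 2 fell (camera adjusted p = 3.91e-05, but adjusted p = 0.248 with an estimated correlation); AT2G20142 rose 8.89-fold and AT5G58120 7.79-fold. SAG101 was the 1 measured member of the salicylic acid synthesis list, and AT2G04400, an enzyme of tryptophan synthesis, the 1 of the camalexin list (1.58 ± 0.13, called).

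Unfolded protein response, oxidative stress and heat shock genes also rose in darkness. Of 8 measured genes of the unfolded protein response, 7 rose in darkness, 7 also adjusted over the list alone (median 1.39, camera adjusted p = 6.63e-06, and 0.0379 with an estimated correlation), among them BZIP60, a transcription factor activated by ER stress (1.81 ± 0.16), and the calreticulin gene CRT1b (1.96). BZIP17 was at 0.28 (adjusted p = 0.389). Of 45 genes of ER translocation and early secretion, 16 rose and 1 fell (camera adjusted p = 0.0116, but adjusted p = 0.0990 with an estimated correlation), with AT3G05230 at 1.26 ± 0.16 and AT1G29310 at 1.21 ± 0.16. All 4 measured oxidative stress genes rose, 4 also adjusted over the list alone (camera adjusted p = 6.57e-06, and 0.0138 with an estimated correlation), among them the alternative NADH dehydrogenase gene NDB2 (7.59-fold) and the glutathione S-transferase gene GSTU25 (9.85-fold). All 3 measured heat shock genes rose, also adjusted over the list alone (camera adjusted p = 0.00247, but adjusted p = 0.192 with an estimated correlation), with AT5G51440 (HSP23.5) 7.59-fold and AT1G53540 (HSP17.6C) 6.72-fold higher. In the senescence and autophagy list 3 of 8 members rose, 3 also adjusted over the list alone, and none fell (camera adjusted p = 0.0276, but adjusted p = 0.358 with an estimated correlation), namely the autophagy genes ATG8H (6.87-fold), AT3G61960 (ATG1A, 3.91-fold) and APG8A (2.28-fold). The list's test was at adjusted p = 0.0786 without normalization, 0.0742 with median scaling and 0.0654 with hybridization control scaling.

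Chloroplast genes of the nucleus fell in darkness. All 5 measured photosynthesis genes were lower, 5 also adjusted over the list alone (median -1.20, camera adjusted p = 0.00221, but adjusted p = 0.251 with an estimated correlation), among them LHCB4.2 and PRK, the phosphoribulokinase gene of the Calvin cycle (-2.15 ± 0.26). All 12 nuclear-encoded photosystem and Calvin cycle genes fell (camera adjusted p = 3.91e-05, but adjusted p = 0.261 with an estimated correlation), as did all 9 nuclear-encoded plastid ribosomal protein genes (median -1.17, camera adjusted p = 6.60e-05, but adjusted p = 0.303 with an estimated correlation), for instance AT4G01310 (-1.61 ± 0.23) and AT2G43030 (-1.29 ± 0.20). Of 102 cytosolic ribosomal protein genes, 4 rose and 3 fell, with a median of 0.01 (camera adjusted p = 0.841). AT5G23900 was lower (-0.88 ± 0.20) and AT2G20450 higher (0.58 ± 0.18), and neither was called without normalization or with hybridization control scaling.

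Genes of sugar, growth and the SnRK1 complex changed in darkness, with no call for their lists by camera. Fry, which does not compare a list with other genes, called the SnRK1 complex (adjusted p = 0.000137), auxin and elongation (0.000547) and sugar lists (0.00113), all lower, the last against a median of 0.56. In the SnRK1 complex list 3 of 4 measured members fell, 3 also adjusted over the list alone (camera adjusted p = 0.0918): the beta subunit gene AKINBETA1 (-1.75 ± 0.17), AT1G15330 (PV42A, -0.73 ± 0.16) and AT4G16360 (KINB2, -0.52 ± 0.12). In the list of SnRK1-activated and starvation genes 2 of 5 rose and 2 fell, 4 adjusted over the list alone (camera adjusted p = 0.841), with the transcription factor gene BZIP53 at 1.58 ± 0.12 and IVD, an enzyme of leucine breakdown, at -1.50 ± 0.16. The sugar list gave 2 higher and 1 lower of 5, with the same counts adjusted over the list alone (camera adjusted p = 0.824): the sucrose transporter gene SWEET11 fell 13.3-fold and the amylase gene AMY1 rose 2.04-fold. In the auxin and cell elongation list 1 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.267), with the expansin gene EXPA8 at -2.79 ± 0.18 and the auxin-conjugating enzyme gene GH3.3 at 2.53 ± 0.26.

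The remaining planned lists were not called by camera in darkness. Fry, which does not compare a list with other genes, called the abscisic acid (adjusted p = 3.02e-05), cell cycle (0.00229), root marker (0.00451) and chlorophyll lists (0.0339), all lower. COR47, a cold and drought responsive dehydrin gene, was the 1 called of 4 abscisic acid and water stress genes, also over the list alone (-2.73 ± 0.13, list camera adjusted p = 0.212), and CHLM the 1 called of 4 chlorophyll and light signalling genes (-1.61 ± 0.20, list 0.613), where 2 were called adjusted over the list alone. The mitotic kinase genes AUR1 (-0.97 ± 0.22) and AUR2 (-0.61 ± 0.19) fell (2 of 3 in the cell cycle list, 3 adjusted over the list alone, list 0.111), EXPA18 fell among 3 root markers, also over the list alone (-1.12 ± 0.21, list 0.212), and AT5G02870 rose in the ribosome list (0.54 ± 0.17, 1 of 3, 2 adjusted over the list alone, list 0.578). Of 4 flavonoid genes none was called, also adjusted over the list alone (list 0.956), with UGT78D2 at 0.27 ± 0.16. Lists with fewer than 3 measured members were not tested: GI of the clock was higher (0.41 ± 0.13), THI2.1 of the jasmonate and ethylene list was at -0.06 ± 0.14 and M17 of the seed list at -0.29 ± 0.40. No member of the trehalose list was analysed here. AUR1, AUR2, GI, AT5G02870 and AT1G15330 were not called without normalization between arrays or with hybridization control scaling, and GI, AT5G02870 and AUR2 also lost their call when single arrays were left out.

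**Figure D1:**
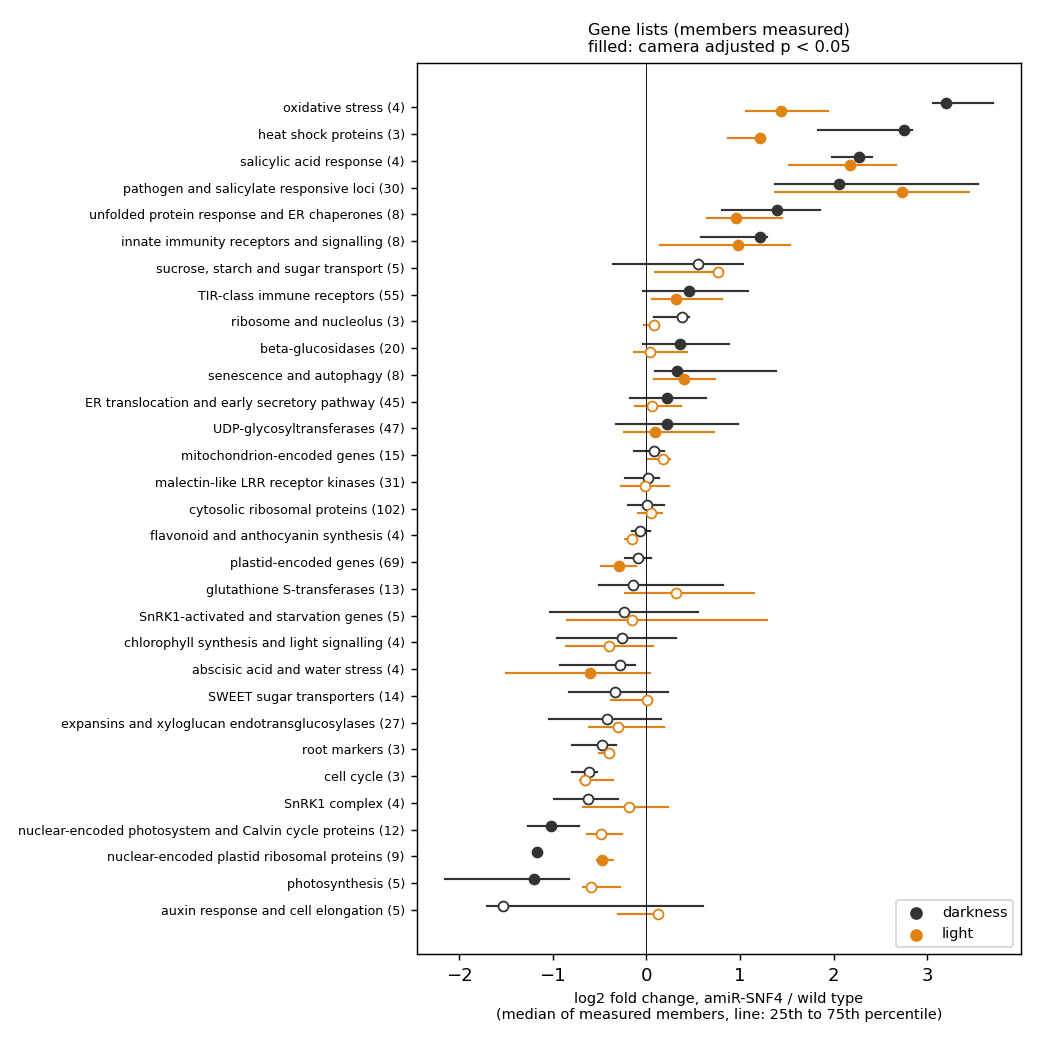
Median log2 fold change of amiR-SNF4 over wild type for the measured members of each gene list (number in brackets), in darkness (grey) and light (orange), with lines from the 25th to the 75th percentile of members and filled points for lists called by camera at the preset correlation. The salicylic acid response list lies at 2.27 in darkness and 2.18 in light, and the photosynthesis list at -1.20 in darkness.

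In light-grown seedlings, silencing again went with higher defence and ER stress genes. SAG101 rose 5.69-fold (log2 fold change 2.51 ± 0.15, SE, n = 3 arrays per group), the transcription factor WRKY53 6.44-fold (2.69 ± 0.16) and BZIP60 4.60-fold, while COR47 fell 5.67-fold. In all, 2550 of 13356 genes differed, 1221 higher and 1329 lower, 958 of them by at least 2-fold (623 higher, 335 lower). Of all genes, 5398 (40.4%) had no overlap between the arrays of the genotypes, where chance gives 10%. Without normalization 1486 were called (713 higher, 773 lower), 1465 of them in the same direction with normalization, and scaling to hybridization controls gave 1729 (1134 higher, 595 lower). The order of the counts in darkness and light depended on the shared spread: fitted with only their own 2 groups on the same normalized values, darkness gave 2961 genes and light 3542.

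Among the named genes, the 5 largest rises in light were those of AT3G28510 (75.8-fold), AT1G21520 (73.5-fold), the lectin-like gene AT5G03350 (67.0-fold), AT3G60420 (57.7-fold) and AT2G30670 (54.3-fold). The largest falls of named genes were those of AT4G29030 (10.1-fold), AT4G22490 (8.78-fold), AT1G12010, an ethylene-forming oxidase gene (7.39-fold), the peroxidase gene AT4G26010 (6.89-fold) and AT4G38690 (6.01-fold). Wild-type signals of the 5 genes that rose lay between 4.07 (AT3G28510) and 6.08 (AT1G21520) on the log2 scale, close to the floor set by the added 16, where folds are understated by unequal amounts, so their order is uncertain. Adjusted p-values of these 10 genes ran from 1.87e-11 for AT3G60420 to 3.14e-05 for AT4G29030.

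Of 4 salicylic acid response genes, 3 rose in light, 3 also adjusted over the list alone (median 2.18, camera adjusted p = 8.17e-05, and 0.0251 with an estimated correlation), among them UGT76B1, a glycosyltransferase of the salicylate pathway (3.58 ± 0.28 on the log2 scale), and AT5G52810 (5.12-fold). BSMT1 was at 0.10 (adjusted p = 0.813). In the innate immunity list 5 of 8 rose and WRKY22 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.00225, and 0.0441 with an estimated correlation); PUB24 was 2.68-fold higher. Of the 30 pathogen and salicylate responsive loci 28 rose and none fell (median 2.73, camera adjusted p = 4.14e-37, and 0.00206 with an estimated correlation), with AT5G52760 39.8-fold higher. Of 55 TIR-class receptors 19 rose and none fell (camera adjusted p = 1.53e-07, but adjusted p = 0.178 with an estimated correlation), among them AT2G20142 (7.01-fold) and AT3G04210 (5.25-fold). AT2G04400 rose by 1.69 ± 0.13.

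Of 8 unfolded protein response genes 6 rose in light, 6 also adjusted over the list alone (median 0.95, camera adjusted p = 1.84e-06, and 0.0367 with an estimated correlation), with ATERDJ3B 3.67-fold higher. All 4 oxidative stress genes rose, also adjusted over the list alone (median 1.43, camera adjusted p = 0.000111, and 0.0251 with an estimated correlation), AT2G21640 6.08-fold and NDB2 3.28-fold. In the heat shock list 2 of 3 rose, 2 also over the list alone (camera adjusted p = 0.0217, but adjusted p = 0.329 with an estimated correlation), namely AT1G53540 (2.32-fold) and AT5G51440 (2.37-fold). The senescence and autophagy list had 3 of 8 higher, 3 also over the list alone (camera adjusted p = 0.0344, but adjusted p = 0.440 with an estimated correlation), with ATG8B at 1.48 ± 0.22 and APG8A at 1.13 ± 0.19, the latter not called without normalization. In the abscisic acid list COR47 and the dehydrin gene LTI30 (-1.16 ± 0.16) fell, 2 of 4, also over the list alone (camera adjusted p = 0.0450, but adjusted p = 0.276 with an estimated correlation). The calls of the last 2 lists were lost without normalization (0.101 for senescence and autophagy, 0.111 for abscisic acid), with median scaling (0.05002 and 0.0592) and with hybridization control scaling (0.0837 and 0.0812). Of 45 ER translocation and secretory genes 8 rose (camera adjusted p = 0.0890), among them AT1G26690 (1.16 ± 0.15) and AT1G29310 (1.01 ± 0.16).

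Of the photosynthesis list, 2 genes were called in light, and the difference between light and darkness was called for 1 of its 5 members, PRK. LHCB4.2 (-1.03 ± 0.23) and PSAN, a photosystem I subunit gene (-0.67 ± 0.20), fell, 2 of 5 in their list and 2 over the list alone (camera adjusted p = 0.0710). Of 12 photosystem and Calvin cycle genes 3 fell and LHCB4.3 rose (1.47 ± 0.13), with PSB27 at -1.07 ± 0.21 (camera adjusted p = 0.0761). Of 9 plastid ribosomal protein genes 1, AT5G24490, fell (-1.56 ± 0.24, list camera adjusted p = 0.0217, but adjusted p = 0.547 with an estimated correlation). Both chlorophyll genes CHLM (-0.99 ± 0.20) and PORB (-0.81 ± 0.26) fell, 2 of 4, also over the list alone (list 0.323). PSAN and PORB were not called without normalization or with hybridization control scaling, nor LHCB4.2 and PSB27 with the latter, and PORB lost its call without any 1 of the 6 light arrays. The photosynthesis list passed the test with median scaling (adjusted p = 0.0260) and without normalization (0.0367), as did the photosystem and Calvin cycle list (0.0201 and 0.0333).

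In the SnRK1 complex list AKINBETA1 (-0.96 ± 0.17) and AT4G16360 (-0.58 ± 0.12) fell in light, 2 of 4 and 2 over the list alone (camera adjusted p = 0.383). In light fry called the SnRK1 complex (adjusted p = 0.0264), cell cycle (0.0264) and root marker lists (0.0217) lower. It called the sugar list higher (0.00785), opposite to the direction fry gave in darkness. The list's median was above 0 in both conditions, 0.56 in darkness and 0.76 in light. For the difference between the effects, camera did not call the sugar list (adjusted p = 0.254), whereas fry did (adjusted p = 0.00298). Of the starvation genes BZIP53 (1.53 ± 0.12) and PPDK (1.28 ± 0.18) rose and 2 fell, 4 over the list alone (camera adjusted p = 0.647). The sugar list had 3 of 5 higher, 3 over the list alone (camera adjusted p = 0.186), with AMY1 at 0.76 ± 0.22 and the starch synthesis gene APL3 at 0.78 ± 0.24. GH3.3 rose 8.84-fold and EXPA8 fell 1.65-fold, 2 called of 5 auxin and elongation genes, also over the list alone (list 0.543). AUR2 fell (-0.75 ± 0.19, 1 of 3 cell cycle genes, 2 over the list alone, list 0.186), and ICL, an enzyme of lipid mobilisation, was 2.46-fold higher. AT5G39850 was the 1 called of 102 cytosolic ribosomal protein genes (1.00 ± 0.21, list camera adjusted p = 0.323). No member was called of the ribosome (PGY1, -0.13 ± 0.11, list 0.827), flavonoid (DFR, -0.32 ± 0.31, list 0.543) and root marker lists (EXPA18, -0.62 ± 0.21, list 0.186, 1 over the list alone), nor were GI (0.07 ± 0.13) or PDF1.2 (-0.15 ± 0.19). Of these genes AT4G16360, APL3, EXPA8 and AT5G39850 were not called without normalization, and AKINBETA1, AT4G16360, EXPA8 and AUR2 not with hybridization control scaling. Leaving out single arrays also ended the calls of APL3, ICL, AMY1, EXPA8 and AUR2.

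**Figure D2:**
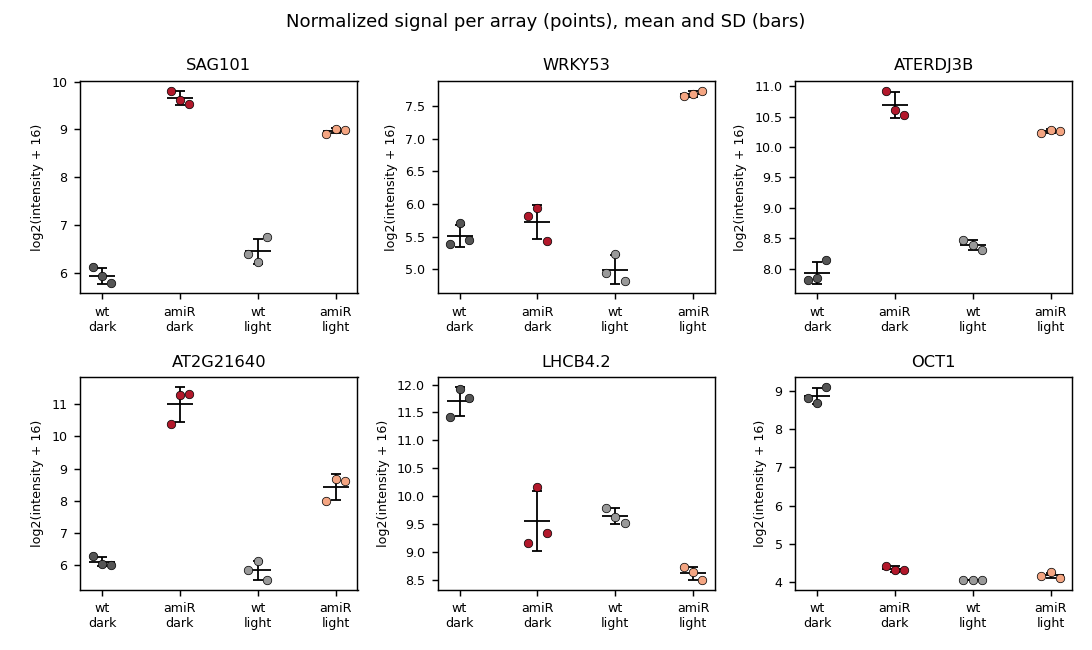
Normalized log2(intensity + 16) of 6 genes on each of the 12 arrays (points, 3 per group) with group means and SD (bars). In SAG101, ATERDJ3B and AT2G21640 all amiR-SNF4 arrays lie above all wild-type arrays in both conditions, WRKY53 separates the genotypes in light, and OCT1 in light lies near the floor of the scale.

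Effects in darkness and light shared most of their direction. Of the genes called in both conditions, 891 were higher in both and 878 lower in both, where independent lists would share 175 and 219, and 57 went opposite ways. The comparisons share no array, but they share the 1 spread of each gene and the normalization. Their calls are therefore not fully independent even without a common effect. Across genes the log2 fold changes correlated at r = 0.719 (Spearman's rho 0.573); genes are not independent replicates.

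The effect of silencing differed between light and darkness for 1066 genes, 543 with a more positive effect in light and 523 with a more negative one. This contrast spans dark and light arrays, so a batch of labelling or hybridization could bear on it. The level of SNF4 was not analysed here, so equal silencing in darkness and light could not be checked. OCT1 had the smallest p: it fell 22.9-fold in darkness, while in light both genotypes lay near the floor of the scale (4.06 ± 0.01 in wild type and 4.18 ± 0.07 in amiR-SNF4, SD, n = 3), where no fall can be measured. GAT1_2.1, a glutamine amidotransferase gene, fell 2.99-fold in darkness and rose 4.50-fold in light. AT5G03350 rose 4.69-fold in darkness and 67.0-fold in light, ATPMEPCRD fell 28.1-fold and 1.83-fold, and AT5G16010 rose 10.1-fold in darkness and was 1.04-fold lower in light. The differences of these 5 genes ran from -3.39 ± 0.21 for AT5G16010 to 4.64 ± 0.18 for OCT1 (log2, SE, n = 3 arrays per group), with adjusted p-values from 4.43e-08 for OCT1 to 2.17e-06 for ATPMEPCRD.

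Among the lists, the 4 oxidative stress genes all had a smaller rise in light (median difference -2.22, camera adjusted p = 1.20e-05, and 0.0270 with an estimated correlation). Heat shock genes (2 of 3 called, camera adjusted p = 0.0188) and beta-glucosidases (3 of 20, 0.0117) also shifted down, while photosynthesis (1 of 5, 0.0172), photosystem and Calvin cycle (2 of 12, 0.000980), plastid ribosomal protein (0 of 9, 0.00974) and auxin and elongation genes (2 of 5, 0.00864) shifted up. With an estimated correlation the adjusted p was 0.505 for heat shock, photosynthesis and photosystem genes, 0.636 for plastid ribosomal genes and 0.250 for beta-glucosidases and for auxin genes. With hybridization control scaling the calls of heat shock (0.0766), photosynthesis (0.0570) and plastid ribosomal genes (0.138) ended, the last also without normalization (0.107). Salicylic acid response genes did not pass this test (camera adjusted p = 0.595), nor did the unfolded protein response (0.222). The pathogen and salicylate responsive loci did not pass it either (camera adjusted p = 0.484), with a median of -0.07 against a test that leaned up. They passed it without normalization (median 0.06, 0.0327) and with hybridization control scaling (0.54, 0.000903). ER translocation genes passed it without normalization (-0.32, 0.0488). Of 8 innate immunity genes, 4 had a more negative effect in light, among them WRKY6 (-1.01, adjusted p = 0.0325), and WRKY53 alone a more positive one (adjusted p = 4.00e-05), 5 and 1 adjusted over the list alone (median -0.73, camera adjusted p = 0.222). Without normalization 278 genes were called (88 more positive, 190 more negative), 276 of them in the same direction with normalization, and the median difference over all genes was -0.12.

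**Figure D3:**
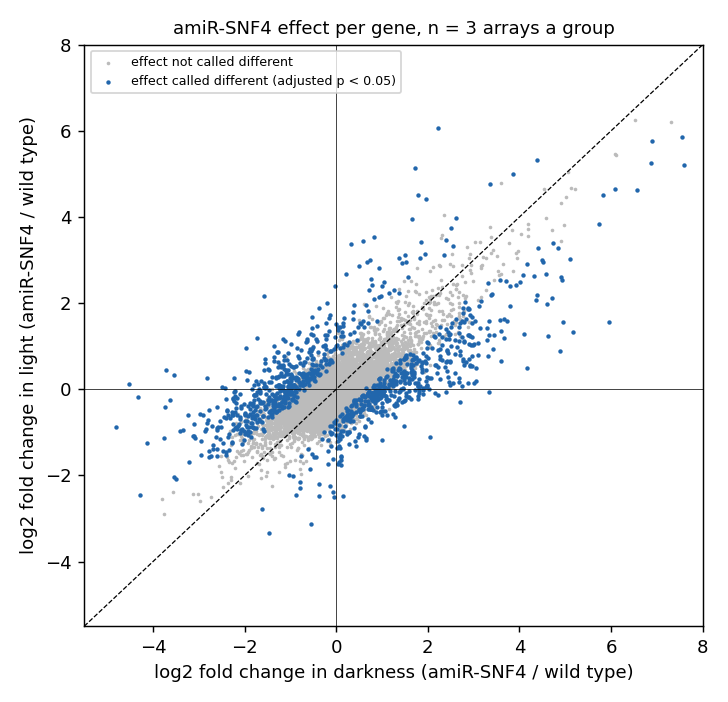
Log2 fold change of amiR-SNF4 over wild type in darkness (x axis) against light (y axis) for each of 13356 genes, with the 1066 genes whose effects were called different in blue and a dashed line of equal effects. Effects in darkness and light correlated (r = 0.719 across genes), with blue points on both sides of the line. Of the blue genes, 823 had the larger absolute effect in darkness.

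Cytosolic ribosomal protein genes were higher in light-grown than in dark-grown wild type. Of 102 cytosolic ribosomal protein genes 84 were higher in light and none lower (median 1.16, camera adjusted p = 1.02e-21, but adjusted p = 0.417 with an estimated correlation). The glyoxylate cycle gene ICL was lower in light (log2 fold change -6.15 ± 0.37, SE, n = 3 arrays per group), the seed storage protein gene PAP85 at -5.21 ± 0.56 and AT5G44440 at -5.05 ± 0.21, and AT1G23130 (42.2-fold), AT3G16670 (4.53 ± 0.25) and AT5G38980 (4.51 ± 0.20) were higher. In all 4656 genes differed, 2464 higher in light and 2192 lower. In amiR-SNF4 4493 differed, 2369 higher and 2124 lower. There the largest rises of named genes were those of AT1G23130, AT5G38980 and AT3G16670 (5.92, 5.29 and 5.03) and the largest falls those of ICL, PAP85 and the seed gene M17 (-4.90, -4.77 and -4.71), and 89 of 102 cytosolic ribosomal protein genes were higher and none lower (camera adjusted p = 2.74e-24, but adjusted p = 0.251 with an estimated correlation).

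All 5 starvation genes were lower in light in wild type (median -1.45, camera adjusted p = 0.000597, but adjusted p = 0.364 with an estimated correlation) and in amiR-SNF4 (median -0.72, 0.00120, but adjusted p = 0.251 with an estimated correlation), IVD by -2.40 and -1.75. The 5 auxin and elongation genes were lower in light in wild type (median -2.21, camera adjusted p = 0.000184, but adjusted p = 0.204 with an estimated correlation), EXPA8 at -2.47 ± 0.18. Of 12 photosystem and Calvin cycle genes 8 were higher in light in wild type (camera adjusted p = 0.0126, but adjusted p = 0.437 with an estimated correlation) and 11 in amiR-SNF4 (2.41e-06, but adjusted p = 0.251 with an estimated correlation), among them SBPASE (2.19 and 2.89). LHCB4.2 went the other way and was lower in light (-2.06 in wild type and -0.93 in amiR-SNF4). In amiR-SNF4 all 4 oxidative stress genes (median -1.71, camera adjusted p = 0.000399, but adjusted p = 0.113 with an estimated correlation) and 7 of 8 senescence and autophagy genes (0.000191, but adjusted p = 0.251 with an estimated correlation) were lower in light. In wild type 5 of 8 senescence and autophagy genes were lower in light as well (camera adjusted p = 0.00800, but adjusted p = 0.417 with an estimated correlation, and 0.0504 without normalization).

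The dark and light arrays also differed in the signal of control RNAs that come from no plant gene. The poly-A control thr averaged 14877.6 on the 6 dark arrays and 163 on the 6 light arrays, a ratio of 91.1, and lys, phe and dap had ratios of 154, 119 and 20.6, with no overlap between dark and light arrays. On the light arrays lys ran from 34.3 to 72.7, where array medians ran from 61.2 to 99.5. The ratios may thus set a signal against background, and whether these controls were added to the light samples was not known here. No group held both dark and light arrays, so the growth condition and a batch of labelling or hybridization cannot be told apart. The share of genes called higher in light also depended on the scaling: without normalization 3649 of 4268 called genes were higher in light in wild type and 2511 of 3258 in amiR-SNF4, with the median of all genes at 0.28 and 0.16. With hybridization control scaling 6619 of 7002 and 7152 of 7520 were higher, with the median of all genes at 0.58 and 0.63. Medians of single lists move with that of all genes: under that scaling the starvation (0.47) and mitochondrion-encoded genes (0.12) in amiR-SNF4 and the SnRK1 complex (0.06) and senescence and autophagy genes (0.23) in wild type were above 0 but still below the median of all genes, and their camera calls ended. The genotype comparisons lie within 1 growth condition each, where the thr control averaged 14660 ± 1919 (SD, n = 3) in wild type and 15095 ± 1006 in amiR-SNF4 in darkness, and 173 ± 89.8 and 153 ± 43.1 in light. The difference between the genotype effects spans both growth conditions, so a batch could bear on it.

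**Figure D4:**
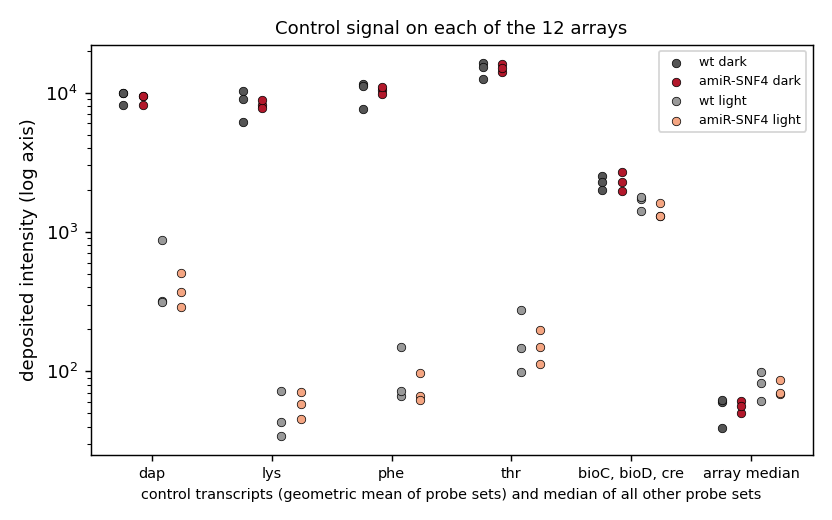
Deposited intensity (log axis) of the poly-A controls dap, lys, phe and thr, of the bioC, bioD and cre hybridization controls, and the median of all other probe sets, on each of the 12 arrays. The 6 dark arrays lie above the 6 light arrays for all 4 poly-A controls, by a mean ratio of 91.1 for thr.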

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

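The tests of compressed fold changes, of the shared spread and of the array batches were chosen after the results they bear on had been seen, while the test of a smaller spread between dark arrays and the counts over other splits were set out before their results, but after the numbers of called genes had been seen.

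The effect of silencing differed between light and darkness by a test of the difference itself in 1066 genes, with differences (light minus darkness, log2) of 4.64 for OCT1, 3.75 for GAT1_2.1, 3.84 for AT5G03350, 3.94 for ATPMEPCRD and -3.39 for AT5G16010. For OCT1 the light arrays of both genotypes lay near the floor of the scale, where no fall could be measured. Of 100 splits of the arrays within each growth condition, 5 gave at least as many genes, the real one included, with up to 1894 in another split, so chance was not excluded by this count. The 4 others each kept the real genotype groups in 1 growth condition, and the 80 splits that kept neither called at most 0 genes, so the splits carry the genotype effect itself. A batch of the arrays and the unknown degree of silencing in each condition stay among the open explanations of these differences.

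More genes were called in darkness (4113) than in light (2550). A smaller spread between dark arrays would need a ratio of median within-group SDs, dark over light, well under 1, but it was 1.51 (0.261 against 0.173), which argues against it. A general compression of fold changes on light arrays would leave few genes with the larger effect in light, but 22.8% of the genes with a differing effect (243 of 1066) had it there, which argues against compression as the whole cause. When each comparison was normalized and fitted with its own 2 groups, darkness called 2998 and light 3478, a ratio of 0.862, and 2961 and 3542 when the normalization over all 12 arrays was kept, so the order of the counts may come from giving noisier dark and quieter light arrays 1 shared spread. The shared spread bears on which genes are called, but it does not alter their fold changes. Among genes with a differing effect, called in both conditions in the same direction, 279 had the larger effect in darkness and 54 in light. A real difference in how light-grown and dark-grown seedlings respond stays open as well.

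The genes changed between light and darkness were weighed against a processing difference. The lowest geometric mean of the poly-A control signals on a dark array was 36.7 times the highest on a light array (8298 against 226), and no group holds both kinds, so a batch of labelling or hybridization and the growth condition cannot be told apart for these genes. The light condition itself stays among the open explanations, untested apart from the batch.

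For the 4 comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05. The real split called 4113 genes in darkness (highest other split 1), 2550 in light (0), 4656 between light and dark wild type (0) and 4493 between light and dark amiR-SNF4 (0), and in each case 1 split, the real one, gave as many.

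Probe sets that the comparisons did not use also carried signal. Of the control probe sets for the 3' end of GAPDH, one was 2.41-fold higher in amiR-SNF4 than in wild type in darkness (adjusted p = 1.07e-05 in limma) and 1.26-fold higher in light (adjusted p = 0.123), and the other 2.01-fold higher in darkness (adjusted p = 4.35e-05), under the main scaling. Of 5 ubiquitin control probe sets, 4 were called higher in amiR-SNF4 in light, from 1.44-fold (adjusted p = 0.00523) to 1.79-fold (adjusted p = 0.000533), and 1 of them also in darkness (1.46-fold, adjusted p = 0.00576), while none of the 6 actin control probe sets was called in darkness or light. Of 8730 probe sets unnamed here, 3732 were called in darkness (1715 higher, 2017 lower) and 2542 in light (1194 higher, 1348 lower), or 42.7% and 29.1%, against 31.6% and 20.1% of the probe sets with a gene name.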

How the results depend on the processing

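The setting without normalization was the design as first written and became an alternative once the array medians were seen; hybridization control scaling, and fits of only the 2 groups compared that kept the normalization over all arrays, were chosen after seeing the data. All other settings were planned, and the cause of a change was not tested unless stated. Without normalization 2282 genes were called in darkness, 1486 in light and 278 for the difference, and with hybridization control scaling 2410 in darkness, 351 for the difference, and 7002 and 7520 between light and darkness in wild type and amiR-SNF4. A pseudocount of 1 gave 637 genes for the difference. Array weights gave 4077 in light. Testing every probe set, which adds unnamed ones, gave 8161, 5353, 2364, 8971 and 8778 in the order darkness, light, difference, wild type and amiR-SNF4. An adjusted p under 0.01 left 1547 in light and 517 for the difference, and a 2-fold minimum left 1771, 958, 1848 and 1760 in darkness, light, wild type and amiR-SNF4. Other count alternatives stayed within 1.5 times of the main count. With an estimated correlation the lists called fell from 14 to 5 in darkness, 12 to 5 in light, 7 to 1 for the difference, 8 to 0 in wild type and 10 to 0 in amiR-SNF4, and fry called 24, 23 and 22 in darkness, wild type and amiR-SNF4. The direction of a list test that passed the threshold turned in 1 case: the sugar list in darkness, with a median of 0.556, leaned lower under fry (adjusted p = 0.00113) and was not called by camera. Hybridization control scaling put the median of all genes at 0.58 and 0.63 between light and darkness in wild type and amiR-SNF4. The medians of 4 lists called lower rose with it, stayed below it and were no longer called: the SnRK1 complex (-0.94 to 0.06) and senescence and autophagy (-0.81 to 0.23) between light and dark wild type, and starvation (-0.72 to 0.47) and mitochondrion-encoded genes (-0.55 to 0.12) in amiR-SNF4.

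Leaving out 1 array gave 3503 to 3956 genes in darkness, 1869 to 2051 in light, 743 to 1128 for the difference, 3760 to 4309 in wild type and 3687 to 4311 in amiR-SNF4, and 13 to 15, 9 to 13, 5 to 8, 7 to 9 and 8 to 13 lists; with 2 arrays in a group the fit still pools the spread over groups. No named gene called under the main setting changed sign under an alternative, and none called only under an alternative had the opposite sign. Sign changes of genes called under neither setting were not counted. Of the gene values, 43 under other settings and 60 under left-out arrays lost their call. Without single arrays, the senescence and autophagy list lost its call in darkness (2 of 6 arrays) and light (3 of 6), the abscisic acid list in light (2 of 6) and the heat shock and photosynthesis lists for the difference (wild type dark array 3). Array numbers did not pair the arrays throughout: deviations of same-numbered arrays correlated at -0.326 to 0.200, and not every array correlated best with its own number. Between dark and light arrays of a genotype, same-numbered arrays all correlated above 0 (0.006 to 0.200). Between the genotypes in darkness they ran from -0.326 to 0.189. Dark wild-type array 3 correlated at 0.363 with dark amiR-SNF4 array 1, and the cause of these correlations was not tested. A replicate block gave 3911, 2345, 902, 4487 and 4293 genes. The level of SNF4 was not analysed here under any setting. Quantile normalization, planned as an alternative, became the main setting. Dim genes limit all counts, as values near the added 16 cannot fall further.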

Other observations

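No test in this part was planned before the annotation was seen; its lists were drawn up from the annotation before any fold change.

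Enzymes of conjugation and detoxification were among the genes higher in amiR-SNF4. Of 47 UDP-glycosyltransferase genes, a family that attaches sugars to hormones and toxins, 16 rose and 7 fell in darkness (camera adjusted p = 0.0110, but adjusted p = 0.192 with an estimated correlation) and 13 rose and 5 fell in light (0.0147, but adjusted p = 0.201 with an estimated correlation). UGT87A2 was 7.57-fold higher in darkness and 6.81-fold in light, and UGT76E12 5.79-fold and 2.90-fold. Of 20 beta-glucosidase genes 7 rose in darkness and none fell (camera adjusted p = 0.00339, but adjusted p = 0.0990 with an estimated correlation), while in light 5 rose (0.188). BGLU25 rose 8.51-fold in darkness and 2.09-fold in light, BGLU15 1.67-fold in light, and BGLU28 5.57-fold in darkness against a value of 0.11 ± 0.17 (log2, SE, n = 3 arrays per group) in light. Glutathione S-transferase genes went both ways, 4 higher and 3 lower of 13 in darkness (camera adjusted p = 0.580; the list's median of -0.14 and the direction of its test differ in sign) and 5 higher and 2 lower in light (0.0710), with GSTU22 6.10-fold and 5.04-fold higher and GSTU26 lower (-2.09 and -1.53 on the log2 scale).

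Cell wall and transport families had no list call by camera in either condition. In darkness fry, which does not compare a list with other genes, called the expansin and xyloglucan endotransglucosylase (adjusted p = 0.00229) and SWEET lists (8.41e-05), both lower. Of 27 expansin and xyloglucan endotransglucosylase genes 4 rose and 12 fell in darkness (camera adjusted p = 0.103) and 3 rose and 6 fell in light (0.279), with EXPA4 8.23-fold higher and XTH16 3.98-fold lower in light. Of 14 SWEET sugar transporter genes 2 rose and 4 fell in darkness (0.179), SWEET3 by 5.23-fold, and SWEET16 was the 1 called in light (2.77-fold lower, list 0.404). Of 31 malectin-like receptor kinase genes 3 rose and 1 fell in darkness (0.694) and 6 rose and 1 fell in light (0.442), with AT1G51890 4.92-fold and 3.53-fold higher, AT1G51790 2.17-fold higher in darkness and AT1G51830 2.17-fold lower in light. Plastid-encoded genes had 2 of 69 lower in darkness, psbE and psbF (0.613), and 4 lower in light (median -0.30, camera adjusted p = 0.0283, but adjusted p = 0.665 with an estimated correlation), among them psbA and psbD, with none called adjusted over the list alone in either condition. Of 15 mitochondrion-encoded genes cox2 rose and ccb382 fell in darkness (0.819) and none was called in light (cox1, 0.39 ± 0.18, list 0.221). The calls of psbE, psbF, psbA, ccb382 and BGLU15 were lost without normalization, that of psbD with hybridization control scaling, and that of the plastid-encoded list when single light arrays were left out.

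Among probe sets unnamed here, the 2 largest rises in darkness were 230-fold and 153-fold and the 2 largest falls 38.8-fold and 35.4-fold. In light the rises were 174-fold and 133-fold and the falls 13.3-fold and 12.9-fold.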
